A study of Mus musculus with 6 samples.

How the data were processed

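HSCs were sorted, RNA was purified with a silica-column kit for small samples and libraries were prepared by Illumina's usual protocol, per the labels' protocols. The submitters' processing notes name Bowtie, DESeq2 1.26.0 and the mouse genome build mm9, with no role for either tool and no Bowtie version. The read counter, the annotation and any filter are not given in the sources used here. The deposited table holds 1 column per library and 1 row per gene, with 19086 rows, and all columns matched a sample. It is named as FPKM, but the deposited values are on a log2 scale. For every library, 2 to the power of the value, minus 1, was a whole multiple of a single step that was the same for genes of any kind, so the values are log2(read count divided by a factor per library, plus 1) and are not divided by gene length. At a tolerance of 0.001 read, 99.7% of the 61139 values above 0 were whole reads. The worth of 1 read was 1.06, 1.90 and 1.98 normalized counts in Zfp521fl/fl replicates 1, 2 and 3 and 0.16, 0.31 and 4.86 in the libraries labelled Zfp521-CKO replicates 1, 2 and 3. The factors were 0.86 to 0.91 of the median-ratio factors computed from the recovered reads. A value above 0 therefore starts at a higher level in the shallow libraries: 3 reads are a log2 value of 0.57 in the deepest library and 3.96 in the shallowest.

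The values that were not whole reads, 213 in 70 genes (115 in control libraries and 98 in libraries labelled Zfp521-CKO), all lay in 1 block of 75 rows. No header or label describes a step that would produce them. For each, shifts of whole log2 units up to 7 and then of 0.1 units were searched for a value that is whole at a tolerance of 0.0001 read. Whole shifts fit 0.33% of random values and shifts in steps of 0.1 fit 2.35%, over 21300 draws. Values as deposited were used for the main tests. The tests were repeated without the 75 rows and with the shifts taken out.

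The test was planned for FPKM as limma on log2(FPKM + 1). Since the deposited values are already log2(normalized count + 1), limma was run on them as they are, and the filter of a mean of at least 1 was applied to the normalized count over 6 libraries, which left 16436 genes. The model (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a trend) held genotype only, with all 6 libraries, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A log2 difference is that of log2(normalized count + 1) and can understate the change of low genes. A difference taken from 0 reads can also overstate it, since 3 reads are a log2 value of 2.07 to 2.80 in the controls. That floor covers counting error only, and the overstatement can be larger where a library lacks reads of a gene for another reason. Gene lists and cell type markers were written before the data were examined, 32 in all, and 604 of their 662 entries matched a row. The 31 with at least 5 members past the filter were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over all 31. Older gene names were matched through a table of RefSeq genes. The reference at hand is of another build than mm9, so no coordinates are given. Shares of reads and the Zfp521 level were compared with a two-sided exact permutation test over the 10 splits of 3 against 3, whose smallest p is 0.1.

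Named genes were chosen by a rule written before the data were examined. They are Zfp521, the 10 genes in each direction with the largest difference among genes past the threshold whose groups do not overlap, and genes of the smallest unadjusted p with groups that do not overlap where fewer than 10 pass. Predicted or unnamed loci, small RNAs, histone genes and immunoglobulin or T cell receptor segments were left out. In a list, the 3 members with the smallest p are named, or up to 4 past the threshold. Always named are Cdkn1a, Cdkn1b, Cdkn1c, Mki67, Ccnd1, Cdk6, Rela, Gata1, Ebf1, Tnfaip3, Nfkbia, Procr, Slamf1, Mecom, Kit, Cd48 and Flt3, and a further gene of this part of the rule is not reported here.

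Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a filter at a mean of 5, median-ratio scaling, quantile normalization and scaling to a total of 1000000, weights per library, no trend, a robust fit, the replicate number as a block, leaving out each library in turn, and other list tests. Added after seeing the data were the table without the 75 rows, the off-step values put back on whole reads, genes with reads in all 6 libraries, a filter at a mean of 100, voom on the recovered reads with and without weights per library, reads thinned to the 3137596 of the shallowest library, voom on the thinned reads, and centring on the median of shared genes.

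The fit was tested on simulated negative binomial counts with the means and factors of the data and 200 changed genes. The changed genes were drawn from those with a mean normalized count of at least 100, so recovery of lower genes was not tested. For the comparison of Zfp521-CKO with Zfp521fl/fl at a dispersion of 0.05, it recovered 99% of genes changed 4-fold and 100% of those changed 16-fold, over 16419 and 16410 genes. At 1.57, the median dispersion of genes with a mean of at least 100, it recovered 0% and 1%, over 16183 and 16179 genes. Changes of 4-fold and 16-fold in single genes of that level therefore lie below what this test finds at this spread. The search for off-step values found 180 of 180 values moved in simulated libraries and none of the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.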

Results

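RNA sequencing was carried out on haematopoietic stem cells (HSCs), sorted as CD150+ CD48– cells of the lineage-negative Sca-1+ Kit+ (LSK) bone marrow fraction of C57BL/6 mice. The cells came from lethally irradiated recipients 2 months after they had received bone marrow from Zfp521fl/fl donors, the control genotype, or from Zfp521-CKO donors, described in the labels as deficient in the zinc finger gene Zfp521. Each genotype had 3 libraries. The labels do not say whether each library came from a separate recipient, so p-values measure the spread between these libraries, which may be technical. The title of the series names quiescence and maintenance of HSCs under stress as its subject. The comparison addresses which genes differ between HSCs labelled Zfp521-CKO and HSCs labelled Zfp521fl/fl.

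Depth differed widely between the libraries. Reads recovered from the deposited values came to 10689480, 7396932 and 7467901 in Zfp521fl/fl replicates 1, 2 and 3. They came to 56237262, 30698602 and 3137596 in the libraries labelled Zfp521-CKO replicates 1, 2 and 3, a range of 17.9-fold between the deepest and the shallowest library. Genes with a value above 0 numbered 10091, 6134 and 7487 in the control libraries and 16674, 14304 and 6449 in the libraries labelled Zfp521-CKO. The 10 most abundant genes took 30.5%, 27.8% and 43.8% of the normalized counts in the controls, and 6.94%, 18.2% and 39.5% in the libraries labelled Zfp521-CKO. Of the 19086 genes listed, 3140 had reads in all 6 libraries, and 6795 had reads in at least 1 library labelled Zfp521-CKO and in no control. Across the 3065 genes with reads in every library and outside the block of rows described next, values of replicates 1 and 2 labelled Zfp521-CKO correlated with Pearson's r = 0.89 and Spearman's rho = 0.87. Replicate 3 correlated with replicates 1 and 2 at r = 0.55 and 0.63 (rho = 0.53 and 0.60), in the range of pairs of controls (r = 0.54 to 0.68) and of pairs across the groups (r = 0.45 to 0.72). These are correlations across genes, which are not independent replicates. Xist had 304 to 34880 reads per library, and each of 3 Y-linked genes had 0 to 6.

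**Figure D1:**
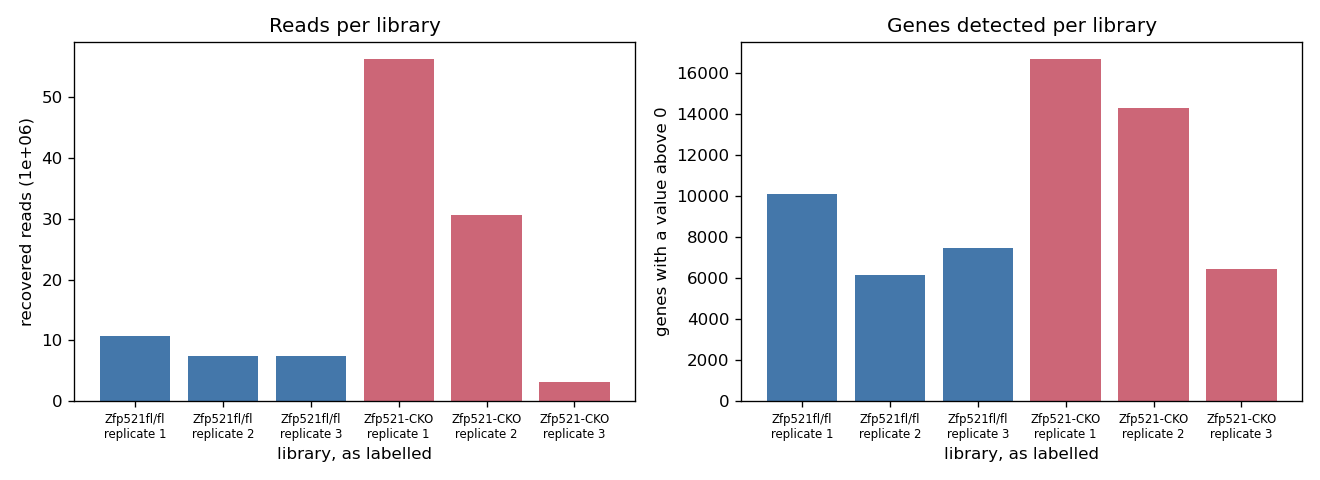
Recovered reads per library (left, axis in units of 1e+06 reads) and genes with a value above 0 (right) for each of the 6 libraries, with Zfp521fl/fl in blue and Zfp521-CKO in red, as labelled. Zfp521-CKO replicates 1 and 2 hold 56237262 and 30698602 reads, and replicate 3 holds 3137596, the fewest of all 6 libraries.

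In 1 block of 75 adjacent rows, 213 values in 70 genes were not whole numbers of reads, within a tolerance of 0.001 read, and are called off-step values here. No such value was found in the rest of the table, where every value above 0 was a whole number of reads. Of the off-step values, 201 (94.4%) became whole reads after a shift of whole log2 units, and the other 12 after a shift in steps of 0.1 units. For 208 of the 213 (97.7%), the deposited value lay nearer to the other libraries of its own group than the value without the shift. Those libraries were taken as deposited and may hold shifts too, so this reference is not independent. The shifts did not mostly widen the difference between the groups: 94 of the 213 (44.1%) did. The median absolute difference in these genes was 2.97 log2 units as deposited and 3.23 with the shifts taken out. The median standard deviation within groups in these 70 genes was 0.65 log2 units as deposited and 1.79 with the shifts taken out, against 1.54 in the other genes with reads in all 6 libraries. All 75 genes of the block had groups whose values did not overlap, compared with 413 of the 3065 other genes (13.5%), where chance gives 10%. The rows of the block are in order of their group difference (Spearman's rho of row order with difference -0.997), while the rows before it are in order of gene identifier, so the block is arranged by the outcome and its 75 of 75 is not the share of a random set of genes. With the shifts taken out, 34 of the 70 genes had groups that did not overlap, and the difference kept its sign in 70 of 70. The block held Rela, Ccnd1, Cdkn1c, Ccr2 and Ndc80, whose differences are given below in both forms, while SDs are of the deposited values. With the shifts taken out, the groups overlapped for Ccnd1, Cdkn1c and Ccr2, and did not for Rela and Ndc80.

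**Figure D2:**
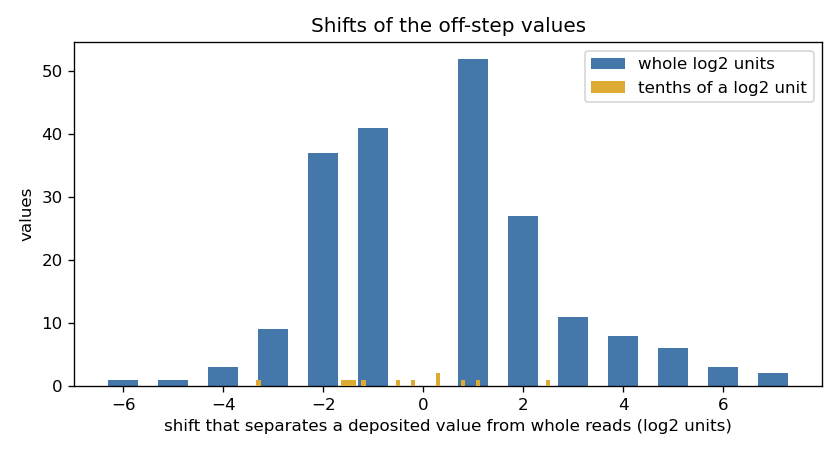
Number of off-step values (vertical axis) by the shift in log2 units that separates the deposited value from whole reads (horizontal axis). The shifts run from -6 to 7 log2 units, and 201 of the 213 are whole units.

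Zfp521 (ENSMUSG00000024420), the targeted gene, had more reads in 2 of the 3 libraries labelled Zfp521-CKO than in any control. The deposited log2 values were 0, 2.74 and 0 in Zfp521fl/fl replicates 1, 2 and 3, which correspond to 0, 3 and 0 reads. They were 7.94, 5.33 and 0 in the libraries labelled Zfp521-CKO replicates 1, 2 and 3, which correspond to 1519, 126 and 0 reads. As a rate this was 26.9 reads per 1000000 (95% exact Poisson interval 25.6 to 28.3) in the library labelled Zfp521-CKO replicate 1 and 4.10 (3.42 to 4.88) in replicate 2, against 0.40 (0.083 to 1.17) in Zfp521fl/fl replicate 2. A count of 0 allows up to 3 reads, or 0.28 and 0.40 reads per 1000000 in Zfp521fl/fl replicates 1 and 3 and 0.95 in the library labelled Zfp521-CKO replicate 3, while the two-sided interval used for the other libraries ends at 0.34, 0.49 and 1.17 there. These intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. The group means were 0.91 ± 1.58 (SD, n = 3) and 4.42 ± 4.05 (SD, n = 3), and the difference did not exceed the spread between libraries (two-sided exact permutation p = 0.4, where the smallest p that 3 against 3 can give is 0.1; limma adjusted p = 0.67). Without the library labelled Zfp521-CKO replicate 1 the difference was 1.75 log2 units instead of 3.51, and without replicate 3 it was 5.72 (limma adjusted p = 0.080). The labels do not state which part of the gene is deleted or which part was counted. Low control values are not particular to Zfp521. Of the 19086 genes listed, 6795 had reads in at least 1 library labelled Zfp521-CKO and in no control. Since the targeted gene does not follow the labels, each direction below is that of libraries as labelled.

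Between the genotypes as labelled, no single gene passed the test. Psmd12, which encodes a subunit of the proteasome, had no reads in any control and log2 values of 10.40, 10.57 and 11.96 in the libraries labelled Zfp521-CKO. It is among the 6795 genes with reads in those libraries and in no control. Thinned to the same total, the controls held 5608 to 9193 genes above 0, against 14608, 12675 and 6449 in replicates 1, 2 and 3 labelled Zfp521-CKO. Absence from the controls is therefore not particular to such a gene, and its difference is not a measured fold change. H2-Q7, a class Ib MHC gene whose reads may be shared with close family members, was at 4.54 ± 0.38 in the controls and 11.78 ± 0.34 in the libraries labelled Zfp521-CKO (SD, n = 3 each). In the other direction, Mpo, which encodes the myeloperoxidase of neutrophil granules, was at 12.88 ± 0.72 in the controls and 8.57 ± 0.56 in the libraries labelled Zfp521-CKO. Cyba, a subunit of the phagocyte NADPH oxidase, was at 14.26 ± 0.38 and 11.71 ± 0.42. None of these had a limma adjusted p under 0.61. Of 16436 genes tested with limma, 0 had an adjusted p under 0.05, and 917 had an unadjusted p under 0.05, of which 836 were higher and 81 lower in the libraries labelled Zfp521-CKO. By chance, a share of 0.05 of the genes tested would reach such a p. Other splits of the same libraries into 3 and 3 gave 195 to 2371 such genes, so the 917 do not set the genotypes apart. The median gene differed by 1.63 log2 units, higher in the libraries labelled Zfp521-CKO, but by 0.03 among the 3140 genes with reads in all 6 libraries, and by 0.04 among the 3065 of them outside the block. It differed by 0.65 without the library labelled Zfp521-CKO replicate 1 and by 2.63 without replicate 3. With quantile normalization the median was 0.22, and 354 genes were higher and 197 lower at an unadjusted p under 0.05, and with each library scaled to a total of 1000000 the median was 0.91.

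The count of changed genes depended on the library labelled Zfp521-CKO replicate 3. Without it, limma called 2509 genes, 2476 higher and 33 lower, and 1761 of them had no reads in any control. With weights per library, where this library received 0.24 and the others 0.82 to 2.11, limma called 1660 genes, of which 1601 were among those 2509. On the recovered reads, limma with voom precision weights called 161 genes, 147 higher and 14 lower, and 130 of the 147 had no reads in at least 2 of the 3 controls. Groups did not overlap for 147 of the 147 and for 6 of the 14. Among the 14 were the neutrophil markers S100a8, S100a9, Camp and Lcn2. In replicate 3 labelled Zfp521-CKO, S100a8 and Camp lay inside the range of the controls, and S100a9 and Lcn2 above it.

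The genes with the smallest unadjusted p among those with groups that did not overlap are given as values, since none was past the threshold (limma adjusted p = 0.61 for each). Gnpnat1 and Med9 had no reads in any control and averaged 10.48 ± 1.87 and 10.01 ± 1.68 (SD, n = 3) in the libraries labelled Zfp521-CKO. Like Psmd12, both are among the 6795 genes without reads in any control. Tonsl, which acts in repair at replication forks, was at 4.47 ± 1.88 in the controls and 12.41 ± 1.27 in the libraries labelled Zfp521-CKO. Lgals3bp was at 2.87 ± 0.71 and 11.45 ± 1.44. Pafah1b2, Vps36, Rnf145 and the adhesion gene Icam2 lay between 0.75 and 1.71 on average in the controls and between 10.71 and 11.51 in the libraries labelled Zfp521-CKO. Among lower genes, Ifitm6 was at 12.83 ± 0.21 in the controls and 4.82 ± 3.56 in the libraries labelled Zfp521-CKO. Pglyrp1, which encodes a peptidoglycan recognition protein of neutrophil granules, was at 14.23 ± 0.58 and 10.54 ± 1.99. Tmsb4x, which encodes the actin-binding thymosin beta-4, was at 17.06 ± 0.30 and 15.17 ± 1.36. Sgms2 and Pilra averaged 9.27 ± 0.94 and 9.18 ± 3.42 in the controls and had no reads in the libraries labelled Zfp521-CKO. Mup3, of a family of near-identical genes, Zfp709 and Met averaged 12.20, 10.01 and 9.47 in the controls against 4.05, 1.36 and 0.71.

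Markers of granulocytes and neutrophils were lower in the libraries labelled Zfp521-CKO as a list. The 15 markers differed by -3.997 log2 units on average, and 14 of 15 were lower (camera with a preset correlation of 0.01, adjusted p = 7.6e-18 over 31 lists). At this preset correlation the list also had an adjusted p under 0.05 in 6 of the 9 other splits of the libraries into 3 and 3. With an estimated correlation of 0.38 between members the call was lost, with an adjusted p = 0.29. Adjusted over the list alone, 3 members were lower and 1 higher, and over all genes tested none passed. The lower ones were Mpo, Ms4a3 (11.60 ± 1.11 in the controls and 4.20 ± 4.34 in the libraries labelled Zfp521-CKO) and Prtn3 (13.66 ± 0.56 and 9.06 ± 3.59), the last named after its values were seen. Gfi1, which encodes a transcriptional repressor active in granulocytes and in HSCs, was the higher one, with no reads in the controls and 7.92 ± 0.94 in the libraries labelled Zfp521-CKO. The list was split in the library labelled Zfp521-CKO replicate 3. There 5 of the 15 markers lay below every control and 4 above, against 12 below and 1 above in each of replicates 1 and 2. The 5, Mpo, Elane, Fcnb, Prtn3 and Ms4a3, lay below every control in all 3 libraries labelled Zfp521-CKO, and Mpo was at 8.25, 9.22 and 8.24. The 4 above every control in replicate 3 were Lcn2, Ltf, S100a9 and Gfi1. The split in replicate 3 thus ran between markers and was not a shift of the list as a whole. The 15 markers took 15.1%, 12.4% and 13.8% of the reads in the controls, and 0.037%, 1.45% and 12.7% in the libraries labelled Zfp521-CKO replicates 1, 2 and 3 (two-sided exact permutation p = 0.2 over n = 3 each, smallest possible 0.1). Shares of some other abundant RNAs also differed between the libraries, in the same order among those labelled Zfp521-CKO but not among the controls: CT010467.1, a transcript not in the lists, took 9.50%, 8.11% and 18.3% in the controls and 1.51%, 5.70% and 16.7% in the libraries labelled Zfp521-CKO, and 7S RNA 2.39%, 2.05% and 5.02% against 0.17%, 1.43% and 3.70% (two-sided exact permutation p = 0.5 and 0.4, n = 3 each). Mitochondrial rRNA took 1.78%, 4.58% and 4.51% in the controls and 0.82%, 4.71% and 5.12% in the libraries labelled Zfp521-CKO. Mitochondrial protein genes took 1.44%, 1.65% and 1.11% in the controls and 2.66%, 1.89% and 1.18% in the libraries labelled Zfp521-CKO, there in the reverse order. Of these, mt-Nd4l, mt-Nd4, mt-Atp6 and mt-Atp8 held off-step values, so their shares depend on taking the shifts out. S100a8, the most abundant of the 15 markers in the controls, took 7.06%, 5.84% and 7.03% there and 0.0061%, 0.67% and 6.03% in the libraries labelled Zfp521-CKO. S100a8, S100a9, Camp and Ngp, genes of mature neutrophils chosen after their values were seen, were at 19.82, 18.94, 18.22 and 17.05 in replicate 3 labelled Zfp521-CKO, inside the range of the controls or, for S100a9, above it. Without replicate 1 labelled Zfp521-CKO the mean of the list was -2.16.

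**Figure D3:**
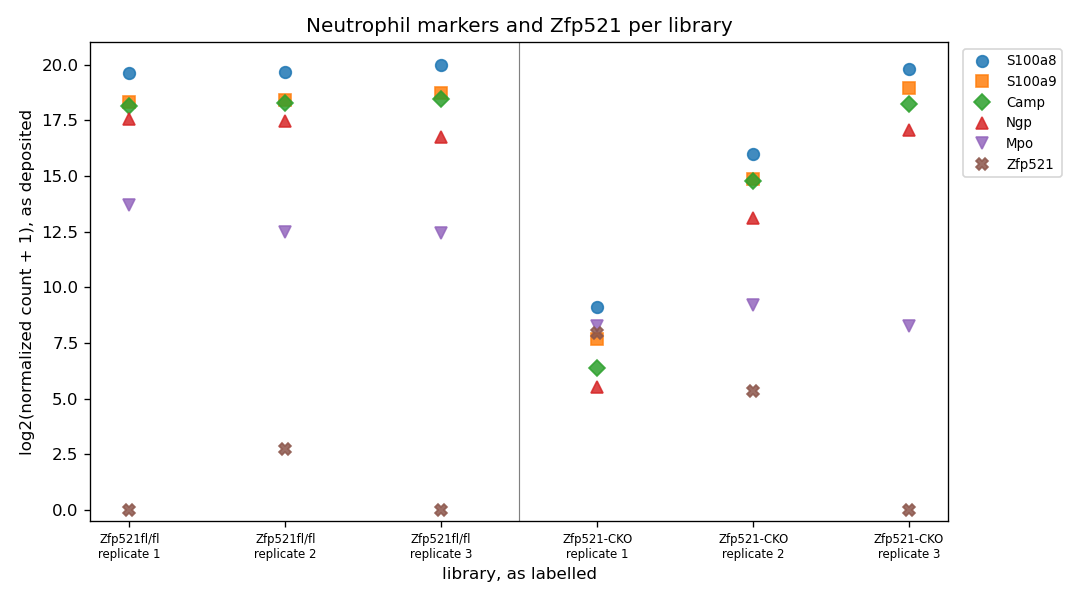
Deposited log2(normalized count + 1) values (vertical axis) of 4 genes of mature neutrophils, of Mpo and of Zfp521 in each of the 6 libraries as labelled (horizontal axis), with 1 symbol per gene and library. S100a8 lies at 9.11 and 15.97 in the libraries labelled Zfp521-CKO replicates 1 and 2 and at 19.82 in replicate 3, and Zfp521 is at 0 in replicate 3.

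Markers of monocytes and macrophages were lower as a list too. The 15 markers differed by -2.49 log2 units on average (camera adjusted p = 1.1e-08, and under 0.05 in 3 of the 9 other splits), and 13 of 15 were lower. With an estimated correlation the call was lost, with an adjusted p = 0.16. No member passed the test, alone or over all genes. Ccr2, the receptor of the chemokine CCL2, was at 10.93 ± 0.85 in the controls and 5.94 ± 0.72 in the libraries labelled Zfp521-CKO as deposited, with 5 off-step values. With the shifts taken out its groups overlapped, with 7.28 in Zfp521fl/fl replicate 3 and 8.12 in replicate 3 labelled Zfp521-CKO. Its difference was -4.98 as deposited and -6.32 with the shifts taken out. F13a1 and Irf8, a transcription factor of the monocyte lineage, differed by -5.23 and -3.03. The share of reads from these markers was 0.85%, 0.78% and 0.38% in the controls and 0.11%, 0.27% and 0.87% in the libraries labelled Zfp521-CKO, so the third of these lay above every control.

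Genes of HSC identity did not pass as a list. Its 32 members differed by 2.54 log2 units on average, 26 of them higher in the libraries labelled Zfp521-CKO, against 1.65 over all genes (camera adjusted p = 0.32). It passed in 1 of 26 alternatives, voom with weights per library and off-step values put back (adjusted p = 0.035), which was added after seeing the data. Esam, Procr and Sult1a1 had the smallest p of the list, with differences of 7.12, 5.48 and 5.81. Procr, which encodes the HSC surface marker EPCR, and Slamf1, which encodes the sorting marker CD150, had no reads in any control. Procr was at 9.06, 3.41 and 3.96 in the libraries labelled Zfp521-CKO, and Slamf1 at 6.71, 0 and 0. Kit and Mecom differed by 3.68 and 3.04, Flt3 by 4.80 and Cd48, whose product the sort excludes, by -2.47, all with a limma adjusted p of at least 0.61. The members of this list took 0.047%, 0.18% and 0.056% of the reads in the controls and 0.25%, 0.27% and 0.036% in the libraries labelled Zfp521-CKO, where the neutrophil markers took 0.037%, 1.45% and 12.7%.

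Regulators of quiescence and self-renewal and genes of the cell cycle did not pass either. The 30 quiescence regulators differed by 2.50 log2 units on average, with 25 higher (camera adjusted p = 0.34), and Gfi1, Cdkn2c and Ndn had the smallest p, with differences of 7.92, 6.28 and 5.80. Of the Cip/Kip inhibitors of cyclin-dependent kinases, Cdkn1a was at 5.15 ± 4.70 in the controls and 4.41 ± 3.94 in the libraries labelled Zfp521-CKO (SD, n = 3). Cdkn1b differed by -4.99 (limma adjusted p = 0.61). Cdkn1c, with 5 off-step values, differed by -1.35 as deposited and by -2.45 with the shifts taken out (limma adjusted p = 0.77 and 0.68). In the library labelled Zfp521-CKO replicate 1, 2 shifts in steps of 0.1 units fitted its value and the first found was used. The -2.45 depends on this choice, and with the shifts taken out its groups overlapped. The 35 genes of the G1/S transition differed by 2.41 on average, with 30 higher (camera adjusted p = 0.32), and Tyms, Chaf1b and Pcna led it at 7.85, 7.39 and 5.45. This list passed with quantile normalization (adjusted p = 0.013) and, in an alternative added after seeing the data, over genes above 0 in all 6 libraries (0.043). It did not pass with an estimated correlation of 0.24 (camera adjusted p = 0.86) or with fry (adjusted p = 0.52). Its members took 0.25%, 0.13% and 0.25% of the reads in the controls and 0.58%, 0.43% and 0.38% in the libraries labelled Zfp521-CKO (two-sided exact permutation p = 0.1, the smallest possible). The same p was reached by p53 targets, immediate early genes and dendritic cell markers, so by 4 of 32 lists, where chance gives 10%. Ccnd1, which encodes cyclin D1, had 4 off-step values and differed by 2.68 as deposited and 3.68 with the shifts taken out (limma adjusted p = 0.61 and 0.62). Cdk6 differed by 0.36, and this turned to -0.35 without Zfp521fl/fl replicate 2 and to -0.20 without the library labelled Zfp521-CKO replicate 3. The 28 genes of G2/M and mitosis differed by 1.47 (camera adjusted p = 0.62). Bub1b had no reads in the controls and 7.06, 6.58 and 10.25 in the libraries labelled Zfp521-CKO. Ndc80 had 4 off-step values and differed by 5.21 as deposited and 5.88 with the shifts taken out, and Ccna2 differed by 5.54. Mki67, the gene of the proliferation marker Ki-67, differed by 1.58 with an SE of 1.82, and by -0.23 without Zfp521fl/fl replicate 2.

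Rela, which encodes the NF-kB subunit p65, was at 4.08 ± 0.25 in the controls and 9.68 ± 0.47 in the libraries labelled Zfp521-CKO (SD, n = 3, limma adjusted p = 0.61). It held 3 off-step values, so both SDs are partly of shifted values. With the shifts taken out, Zfp521fl/fl replicates 2 and 3 were at 2.26 and 2.80, and replicate 3 labelled Zfp521-CKO was at 12.15. Rela differed by 5.61 as deposited and by 7.27 with the shifts taken out. It belonged to the list of known partners of Zfp521, which does not hold Zfp521 itself and of which 14 members differed by 0.53 on average (camera adjusted p = 0.32), with Mta2 at -3.25 and Gata1 at 3.31. No row was used here for Ebf1. The 29 targets of NF-kB and TNF differed by 1.38 (camera adjusted p = 0.57). Ier3, Tnfaip3 and Icam1 differed by 6.90, 5.80 and 5.74, and Nfkbia, the gene of the NF-kB inhibitor, by -1.73. The 23 immediate early genes differed by 0.36 (camera adjusted p = 0.32), with Klf4 at -6.79, Ier3 at 6.90 and Atf3 at -7.14.

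The remaining lists did not pass in the main test. Erythroid markers came closest, with 13 members that differed by 0.31 on average, below the 1.65 of all genes (camera adjusted p = 0.054), and the globin genes Hba-a1, Hbb-bs and Hba-a2, near-identical copies in part, at -2.65, -2.06 and -2.70. The erythroid list passed in 12 of 26 alternatives, with an adjusted p of 0.048 and 0.041 at pseudocounts of 0.1 and 0.01, 0.032 with no filter, 0.048 with scaling to 1000000, 0.046 with weights per library, 0.032, 0.032 and 0.027 without Zfp521fl/fl replicates 2 and 3 and Zfp521-CKO replicate 3, and, in alternatives added after seeing the data, 0.0499 without the 75 rows, 0.018 and 0.035 with voom without and with weights, and 0.047 with thinning. The erythroid list did not pass with an estimated correlation (camera adjusted p = 0.86), with camera on ranks (0.25) or with fry (adjusted p = 0.89, direction up). For 14 of the 31 lists the camera direction was down while the mean difference was above 0, because the test sets a list against all other genes. The mean differences were -1.56 for mast cell and basophil markers and -0.78 for T and NK cell markers, with camera adjusted p = 0.11 and 0.21. Camera adjusted p was 0.32 for adhesion and niche retention, p53 targets, hypoxia response, and ribosome biogenesis and MYC targets, whose mean differences were 0.51, 2.58, 2.69 and 2.25. The last of these passed with quantile normalization (0.022) and over genes above 0 in all 6 libraries (0.022), and mast cell and basophil markers passed with no filter (0.032) and without Zfp521-CKO replicate 2 (0.032). Cytosolic ribosomal proteins passed as higher with quantile normalization (0.013) and as lower with centring (0.0032). It was 0.43 for the interferon response, 0.49 for apoptosis and necroptosis, and 0.54 for oxidative phosphorylation. It was 0.57 for HOX and MEIS genes, stromal and endothelial markers, cytosolic ribosomal proteins, dendritic cell markers, redox defence and the unfolded protein response. It was 0.64 for the heat shock response, 0.73 for megakaryocyte markers and HSC ageing genes, 0.74 for lymphoid-primed progenitor markers and the TGF-beta response, and 0.92 for glycolysis. Adjusted over the list alone, Cat, which encodes catalase, was the only further member of any of these lists to pass, at 0.55 ± 0.95 in the controls and 10.05 ± 1.38 in the libraries labelled Zfp521-CKO. B lymphoid markers had fewer than 5 members past the filter and were not tested.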

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

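Alternatives that concern the 75 rows, shared genes, voom, thinning, centring and the filter at a mean of 100 were chosen after seeing the data. The count of changed genes was 0 in the main test and under most alternatives, with these exceptions. Quantile normalization gave 17 genes (5 higher, 12 lower in the libraries labelled Zfp521-CKO), weights per library 1660 (1632 higher, 28 lower), voom 161 (147 and 14), voom on thinned reads 128 (125 and 3), and voom with weights per library and off-step values put back 2048 (2008 and 40). Leaving out 1 library gave 0 to 2509 genes (0 to 2476 higher, 0 to 33 lower), and only the fit without Zfp521-CKO replicate 3 gave any. The cause was not tested. Genes at an unadjusted p under 0.05 numbered 495 to 3785 when leaving out 1 library. Without the 75 rows, or with off-step values put back, 0 genes were called, and 871 and 895 had an unadjusted p under 0.05, against 917. The number of shifted lists was 2, and it was 3 with pseudocounts of 0.1 and 0.01, scaling to 1000000, weights per library, without the 75 rows, voom, thinning and centring, 4 with no filter on low values, 5 with quantile normalization, 4 with genes above 0 in all 6 libraries, 4 with voom with weights per library and off-step values put back, and 0 with an estimated correlation or with fry. It was 2 to 3 when leaving out 1 library. The cause of these moves was not tested. The neutrophil list kept its direction in 29 of 29 alternatives and its call in 27, with means from -5.43 to -2.16. The monocyte list did so in 29 and 27, with means from -3.71 to -1.76. The calls were lost with an estimated correlation, with means of -3.997 and -2.49 as before and adjusted p = 0.29 and 0.16, and with fry (adjusted p = 0.45 for each), which does not set a list against other genes. The Zfp521 difference was not past the threshold in any of 24 alternatives and ran from 0.45 to 5.81, with adjusted p from 0.080 to 0.97. With the replicate number as a block, 0 genes and 2 lists were called, and the block changed no other call. The numbers were not taken to pair the libraries, since the labels do not say that a number marks a shared donor, recipient, batch or day. Deviations of samples with the same number correlated at 0.12, -0.0030 and -0.030, and those with different numbers at -0.10 to 0.072. With 3 libraries per group these correlations depend on each other and cannot decide whether the numbers pair. For single named genes, 1480 values under alternatives stayed on the same side of the threshold with the same direction, and 128 passed it in the same direction, each with weights per library, quantile normalization, voom in any of its 3 forms, or without Zfp521-CKO replicate 3. Of the named genes, 4 changed direction under some alternative. Cdkn1a was at 0.069 with weights per library and 0.042 with voom with weights, and at -3.32 to 1.47 when leaving out 1 library. Cdk6 was at -0.0087 with voom with weights, -0.14 with centring, and -0.35 to 0.89 when leaving out 1 library. Cd48 was at 0.59 with voom with weights, and Mki67 at -0.23 to 3.19 when leaving out 1 library. After thinning, the libraries labelled Zfp521-CKO replicates 1, 2 and 3 had 14608, 12675 and 6449 genes above 0 and the controls 5608 to 9193, and the median gene differed by 1.63. Thinning moved 1955 of 16436 differences by over 0.5. Depth limits the shallowest library most, where 3 reads are a log2 value of 3.96.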

Other observations

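All tests in this part were chosen after the results they bear on had been seen, and the gene lists alone were fixed before. For the neutrophil markers, the tests of depth and of neutrophil RNA and their bounds were set with the read counts in view, in place of earlier ones on thinned libraries (mean of the list -4.05, camera adjusted p = 2.9e-16) and on the ratio of S100a9 to S100a8 alone, which had counted for neutrophil RNA.

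Off-step values raise the question of how they arose. Rounding or the number format of the table would place them in rows all over it. The block was drawn from the first to the last of these values, so 213 of 213 lie inside it by definition. What argues against this explanation is that the block spans only 75 of the 19086 rows. A correction per gene or per group would give the libraries of a group a common shift, but in 70 of 70 genes libraries of a group differ in their shift. Single values moved by whole log2 units after normalization remain a candidate explanation, since 94.4% return to whole reads that way against 0.33% of random values. What moved them is not recorded, and no biological explanation was tested.

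Of the 15 neutrophil markers, 12 were below every control in each of the libraries labelled Zfp521-CKO replicates 1 and 2, and 5 in replicate 3. Depth alone is argued against for replicates 1 and 2, because 10 of the 15 markers had fewer reads in both of these libraries, the 2 deepest, than in every control, which deeper sequencing cannot produce. RNA of neutrophils in some libraries could contribute and stays open, though the sort of lineage-negative cells is meant to remove neutrophils: the ratio to S100a8 reads varied under 10-fold over 6 libraries for 6 of the 14 other markers (S100a9 1.48-fold, Camp 2.94-fold, Ngp 3.05-fold) while the share of S100a8 varied 1157-fold. It varied more, or had libraries with 0 reads, for the other 8, such as Mpo at 1687-fold. This count cannot decide the question, since a marker with 0 reads in a library has no finite range. Genes regulated together inside HSCs would also keep a ratio. In the controls, though, the markers took 15.1%, 12.4% and 13.8% of reads, against 0.047%, 0.18% and 0.056% for HSC identity genes. In the libraries labelled Zfp521-CKO the markers took 0.037%, 1.45% and 12.7%, against 0.25%, 0.27% and 0.036%. Whether HSCs themselves could give such shares of neutrophil markers was not tested. The genotype stays open and cannot be told apart from RNA of neutrophils, since in replicate 3 the markers took 12.7% of reads, inside the control range, while 5 of them were below every control in all 3 libraries.

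Zfp521 reads were found mainly in libraries labelled as knockout. Depth is argued against as the whole cause, since after thinning all libraries to the same total 89 reads remained in the libraries labelled Zfp521-CKO and 1 in the controls. Exchange of the labels of the 2 groups could produce this and stays open, because 2 of the 3 libraries labelled Zfp521-CKO had over 3 reads. The 0 reads of replicate 3, against 78 and 11 in replicates 1 and 2 thinned to its total, are of a single library and cannot decide it. Reads from a part of the gene left after deletion could give the 1519 reads of replicate 1 but do not bear on the low control values, and a table with 1 value per gene cannot decide it. After thinning, the controls and replicate 3 labelled Zfp521-CKO had 5608 to 9193 genes above 0, against 14608 and 12675 in replicates 1 and 2. Their shares of reads from HSC identity genes were 0.036% to 0.18%, against 0.25% and 0.27%. Whether this accounts for their few Zfp521 reads was not tested.

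The 6 libraries have 10 splits into 3 and 3, too few for a share under 0.05. For changed genes, in total and in each direction, the real split gave 0 and the highest other 0. Every split must give at least 0, so this comparison was fixed in advance and cannot decide anything. For shifted lists, 6 splits gave as many, with 2 in the real split and 5 as the highest other. For voom, 3 splits gave as many, with 161 in the real split and 1046 in the split of Zfp521fl/fl replicate 1 and Zfp521-CKO replicates 1 and 2 from the rest, which points to a structure of the samples. The 4 splits with the most genes (1046, 374, 161 and 101) keep Zfp521-CKO replicates 1 and 2 together, and the others gave at most 24. On thinned reads the split with 1046 gave 1141 and the real one 128, so the difference in read number does not by itself account for this structure. For the neutrophil and monocyte lists, 1 split each, the real one, had as small an adjusted p, with 17.1 and 7.98 as -log10 of it and 12.2 and 7.33 as the highest others. The neutrophil list was under an adjusted p of 0.05 in 6 of the 9 other splits and the monocyte list in 3, so a call at the preset correlation does not by itself set the real grouping apart.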
